A study of Mus musculus with 4 samples.

How the data were processed

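The samples were group 2 innate lymphoid cells (ILC2s) sorted from the mouse colon. The culture medium held the survival cytokines IL-2 and IL-7 and the alarmins IL-33 and IL-25. There were 2 control samples and 2 samples exposed for 16 h to FK866, a small-molecule inhibitor of NAMPT. Per the labels' protocols, total RNA was taken with TRIzol, full-length cDNA was made with the SMART-Seq HT kit, and paired-end libraries were made with the Nextera XT kit. This cDNA chemistry primes on poly(A) tails and does not mark the strand.

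The deposited table holds raw read counts per Ensembl gene ID for 4 libraries, as whole numbers, and the unit was read from the values. Per the submitters' processing notes, cutadapt 1.9 and HISAT2 2.2.1 were used with build mm10. The program that counted reads over genes, its annotation release, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Because the libraries do not mark the strand, reads of a gene and of an overlapping or antisense neighbour cannot be told apart, whatever the strand setting. Reads of near-identical copies may be split between them.

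Gene names, positions, transcript lengths and GC content came from GENCODE M21, on the same build as the processing notes name (GRCm38, mm10). Of 55487 gene IDs in the table, 55141 had a symbol. The other 346 held between 0.0771% and 0.0907% of the counts of a library and stayed in the tests. Library totals were 37841233 and 32540325 counts for control replicates 1 and 2, and 27617750 and 32241615 for FK866 replicates 1 and 2. The group and replicate number of each library were read from its title.

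Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided), with TMM scaling and a model with treatment as its only term. Low counts were filtered by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 19194 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Expression is given as CPM (the share of a library held by a gene, with the library total multiplied by its TMM factor), as mean ± SD over 2 libraries. Fold changes are FK866 over control, and their standard error (SE) is the size of the log2 fold change divided by the square root of F. No label says that the replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. The libraries of each group differed by more than sampling noise, with a chi-square per degree of freedom of 36.7 between the controls and 19.7 between the FK866 libraries, and each was counted as 1 sample.

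Before the data were examined, 39 gene lists with 934 memberships were fixed: 28 of pathways, 9 of markers of other cell types and 2 of RNA quality. All but 3 members matched the table. The 38 lists with 5 or more measured genes were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares the genes of a list with all other genes. It was repeated with a correlation estimated from the data, and fry, which tests whether the genes of a list move on balance in one direction, was run beside it. The estimated correlation rests only on the differences between the 2 libraries of each group and is imprecise. A list that fails with it is therefore not shown to be unchanged. Within each list, calls were counted over all genes tested and also adjusted over the list alone. Another 6 gene families were tested only after they had been noticed in the data.

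The rule for genes named in the text, also fixed before the data were examined, took 14 genes of interest. To these it added the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean log2 CPM of at least 3 and no overlap between the groups, predicted genes and pseudogenes excluded. It further took up to 4 called members with the smallest adjusted p from each pathway list, or the 2 most abundant where none was called, and up to 3 abundant members of each marker list. The marker genes were narrowed after the counts were seen to those with a mean log2 CPM of at least 3. Genes outside the rule are said to be so where they appear. Some genes are not reported here, and for that reason the test for an admixture of ILC3s was reduced from 3 genes to 2.

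The procedure was checked on simulated counts drawn from the means and library sizes of the real samples, with 200 genes changed by known amounts. The changed genes were picked among those with a mean log2 CPM above 2, so recovery of less expressed genes was not measured. For FK866 against control, over 19194 genes, 67 of 100 genes changed 2-fold and 99 of 100 changed 4-fold were recovered, and 14 of 180 calls were false. Of the simulated lists, the 1 that was shifted was called and 0 of 30 random lists were. The simulated genes were drawn independently, so this check does not cover lists whose genes vary together. Real lists did so, with an estimated correlation of 0.78 for NF-κB response genes, for example. A planted length trend of 0.25 per log2 unit was 0.246 before correction and 0.0032 after it.

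The alternatives fixed in advance were 3 other scalings, no filter and a stricter filter (at least 10 counts in 2 samples and a mean log2 CPM of at least 1), DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, leaving out mitochondrially encoded genes, and a test against a 1.5-fold change (glmTreat). A fit without 1 library has 1 group with a single sample, which is then assumed to vary like the other group. After the data were seen, a fit was added in which each library's trend on transcript length and GC content (natural splines with 4 degrees of freedom, fitted on genes with a mean log2 CPM above 2) was removed through offsets. Overlaps between the exons of named genes and those of other annotated genes were counted on either strand.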

Results

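RNA sequencing was used to measure gene expression in ILC2s of the mouse colon, tissue-resident lymphocytes that lack antigen receptors and secrete type 2 cytokines such as IL-5 and IL-13. The cells were cultured in activating cytokines either without FK866 (control, n = 2) or with FK866 for 16 h (n = 2). FK866 inhibits nicotinamide phosphoribosyltransferase (NAMPT), the rate-limiting enzyme that salvages nicotinamide into NAD+, so the comparison asks how transcription in activated ILC2s differs when this route is blocked. Library totals ranged from 27617750 to 37841233 gene counts, and 96.5% to 97.1% of the counts of each library fell in protein-coding genes. FK866 replicate 2 stood apart in the number of gene IDs with at least 10 counts, 22461 against 17152 to 18667 in the other libraries. Its total was close to that of control replicate 2. Its share of counts in noncoding genes was 0.99%, against 0.72% to 0.86%. The source of this difference was not tested. The first principal component, with 48.6% of the variance, separated FK866 from control libraries, and the second, with 32.0%, separated replicate 1 from replicate 2 in both groups.

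FK866 changed the expression of 2534 of 19194 tested genes, 1020 upward and 1514 downward (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 458 rose and 602 fell by at least 2-fold. The called genes were 13.2% of those tested, and 2450 of them lay among the 11047 genes that pass the stricter filter. The counts of called genes per list given below are to be read against this share, since a few calls in a list of expressed genes are not by themselves a result about that list. Among moderately and highly expressed genes the steepest rise was that of Cxcr4 (ENSMUSG00000045382, mm10 chromosome 1, 128588199 to 128592293, minus strand), the receptor for the chemokine CXCL12, from 0.989 ± 0.314 to 44.6 ± 4.05 CPM (mean ± SD, n = 2). Its log2 fold change was 5.48 ± 0.28 (SE) with an adjusted p of 0.000118. It was followed by Arrdc4, an α-arrestin that restrains glucose uptake (log2 3.52), the metallothionein gene Mt1 (3.50), the transcriptional repressor gene Bcl6 (3.38), Tent5a (3.37), the melanocortin receptor gene Mc5r (3.17), Zfp948 (2.96) and Casz1 (2.95). The deepest falls were in Cited4 (log2 -2.79), the replication licensing gene Cdc6 (-2.61), Jrk (-2.55), the cytokine gene Lif (-2.49), the replication factor Mcm10 (-2.39), Rmi2 (-2.27), Lbhd1 (-2.26) and the interferon-induced gene Oas3 (-2.13). Leaving out 1 library moved the fold change by over 1.5 times for Mt1 (4.17 without control replicate 1), Bcl6 (4.10 without control replicate 2) and Cited4 (-3.41 without FK866 replicate 2). For Lbhd1, 38.4% of the exon bases lie in exons of other annotated genes, so its counts may be shared with them.

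Nampt itself (ENSMUSG00000020572, chromosome 12, 32819545 to 32853349, plus strand) stood at 74.5 ± 4.96 CPM in controls and 62.8 ± 2.66 CPM in FK866 libraries, a log2 fold change of -0.25 ± 0.14 (SE) that did not pass the test (edgeR adjusted p = 0.301). None of the 19 measured genes of NAD+ synthesis passed, either over all genes or adjusted over the list alone (camera adjusted p = 0.416). NAD kinase (Nadk) had a log2 fold change of -0.09 and the mitochondrial NAD+ carrier Slc25a51 of -0.45 (adjusted p = 0.0678; called lower without control replicate 2, by DESeq2 and with the length and GC trend removed). At an unadjusted p under 0.05, 5370 of all tested genes stood out. Among 23 measured enzymes that consume NAD+, 3 rose and 7 fell (3 and 8 adjusted over the list alone), without a shift of the list as a whole (camera adjusted p = 0.0939). Parp12 fell (log2 -1.35) and the tankyrase gene Tnks rose (0.96). Without FK866 replicate 1 the list was called lower (adjusted p = 0.039). Only 3 of these enzymes were called lower without control replicate 2, without FK866 replicate 1 or without FK866 replicate 2.

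**Figure D1:**
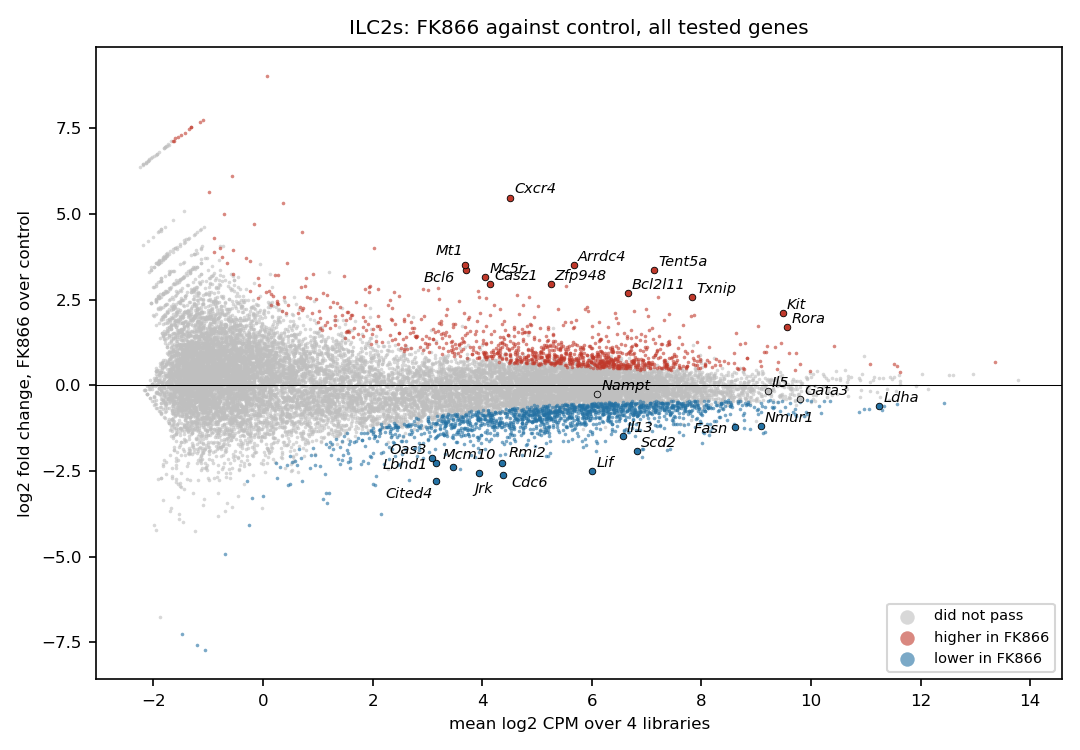
Log2 fold change of FK866 over control against mean log2 CPM over the 4 libraries, one point per tested gene, with genes that passed the edgeR test in red (1020 higher) and blue (1514 lower) and the others in grey. Cxcr4 lies at 5.48, Kit and Rora are high among abundant transcripts, and Nampt, Gata3 and Il5 lie in grey near the zero line.

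Genes of DNA replication fell almost as a block. Of 33 measured genes of the G1 and S phases, 28 were lower in FK866 and 0 were higher, with a median log2 fold change of -1.16 (29 lower adjusted over the list alone). Besides Cdc6, which fell from 35.8 ± 4.56 to 5.87 ± 0.178 CPM, the list held thymidylate synthase (Tyms, log2 -1.56) and the helicase subunits Mcm7 (-1.37) and Mcm5 (-1.40). The camera test gave an adjusted p of 3.59e-31, and an adjusted p of 0.60 with an estimated correlation. Of 28 genes of G2 and mitosis, 2 fell, and the list did not pass (median -0.40, camera adjusted p = 0.102). They were Cdc20 (-1.03) and the cyclin gene Ccna2 (-2.28, and between -2.84 and -1.47 as each library was left out). Neither of these 2 calls held without control replicate 1 (0 called in the list) or without FK866 replicate 2 (0 called), that of Cdc20 did not hold without FK866 replicate 1 either, and without control replicate 2 the list was called lower (6 genes, adjusted p = 0.00438), as it was without FK866 replicate 1 (1 gene, adjusted p = 0.0232).

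Of 19 transcripts of cytokine receptor and STAT5 signalling, the pathway through which IL-2 and IL-7 act, 9 fell and 1 rose (11 and 2 adjusted over the list alone). The feedback inhibitor Socs1 fell from 270.6 ± 45.3 to 74.0 ± 18.6 CPM, Osm from 258.9 ± 35.5 to 70.5 ± 12.3 CPM, and the growth-associated genes Ccnd2 and Pim2 by 1.16 and 0.83 on the log2 scale. The list median was -0.50, with a camera adjusted p of 3.09e-05 (adjusted p = 0.72 with an estimated correlation). Of 30 genes of ribosome biogenesis and MYC targets, 9 fell, among them Bop1 (-0.87), and 1, ornithine decarboxylase (Odc1, 0.95), rose (17 and 1 adjusted over the list alone). Their camera adjusted p was 0.000465 (adjusted p = 0.75 with an estimated correlation), while Myc had a log2 fold change of -0.39 ± 0.15 (SE) that did not pass (adjusted p = 0.12) but was called lower without control replicate 2 (-0.53, adjusted p = 0.0401). The count of 9 became 5 without FK866 replicate 1, 1 without FK866 replicate 2 and 18 without control replicate 2. Of 18 heat shock genes, 6 fell and 0 rose (7 and 1 adjusted over the list alone), with Hspa4 at -0.67 and Hsp90aa1 at -0.83 (camera adjusted p = 0.0221; adjusted p = 0.72 with an estimated correlation). The heat shock call was lost without FK866 replicate 2 (3 genes, adjusted p = 0.204) and with the stricter filter (adjusted p = 0.0819).

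Most genes of sterol synthesis fell. Of 24 measured genes of cholesterol synthesis and its regulation, 17 were lower and 0 higher (20 and 0 adjusted over the list alone), with a median log2 fold change of -0.86 and a camera adjusted p of 8.77e-15 (adjusted p = 0.72 with an estimated correlation). Acat2 fell by 1.57, Pmvk by 1.52 and mevalonate kinase (Mvk) by 1.31 on the log2 scale, and the sterol demethylase Cyp51 went from 535.0 ± 47.7 to 243.0 ± 39.1 CPM. Without FK866 replicate 2, 10 of these genes were called. In the list of fatty acid synthesis and lipid storage, 7 of 22 genes fell and 2 rose, the same counts as adjusted over the list alone. Fatty acid synthase (Fasn) went from 547.9 ± 69.0 to 236.3 ± 37.8 CPM, and the desaturase Scd2 and the fatty acid binding protein Fabp5 fell by 1.92 and 1.13 on the log2 scale. The triglyceride-forming enzyme Dgat1 rose (0.99). The list median was -0.03 and its mean -0.24, with a camera adjusted p of 0.0287 (adjusted p = 0.72 with an estimated correlation). That call was lost without FK866 replicate 2 (adjusted p = 0.136), with scaling by library totals (adjusted p = 0.0506) and with the stricter filter (adjusted p = 0.113).

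Of 71 nuclear-encoded genes of oxidative phosphorylation, 18 fell and 0 rose (32 and 0 adjusted over the list alone), with a median log2 fold change of -0.38 and complex I subunits Ndufb3 (-0.93), Ndufb4 (-1.01) and Ndufb7 (-0.76) among them. The camera adjusted p was 4.19e-10 (adjusted p = 0.72 with an estimated correlation). Across 9292 protein-coding genes with a mean log2 CPM above 2, fold changes rose with transcript length (Spearman rho = 0.332 across genes, which are not independent), and these genes are short, with a median transcript of 1005 nt. With the length and GC trend removed, an alternative chosen after seeing the data, the list no longer passed (adjusted p = 0.064, with 11 genes lower and 2 higher), and Ndufb3 was at -0.53 and Ndufb4 at -0.66. The number called was 5 without either FK866 library and 34 without control replicate 1. Of 11 mitochondrially encoded subunits, mt-Co1 rose (0.62, or 0.96 with the trend removed), a call lost without control replicate 1, without FK866 replicate 2 or with no filter, and the list did not pass (median -0.47, camera adjusted p = 0.334). Without control replicate 1, however, 6 of the 11 were called lower and the list passed (adjusted p = 2.67e-05).

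Of 22 genes of the TCA cycle, 3 fell and 0 rose, also when adjusted over the list alone, including fumarase (Fh1, log2 -1.34) and Suclg1 (-0.61), and of 22 genes of fatty acid oxidation 5 fell and 0 rose, likewise, including Acsl1 (-1.31) and Cpt2 (-0.89). Their camera adjusted p-values were 0.0195 and 0.0287 (adjusted p = 0.72 with an estimated correlation for each). Suclg1 was not called without FK866 replicate 1 or FK866 replicate 2, nor Cpt2 without FK866 replicate 1. Both list calls were lost without FK866 replicate 2, with the stricter filter (camera adjusted p = 0.191 and 0.242) and with the length and GC trend removed (0.299 and 0.194). That of fatty acid oxidation was also lost without control replicate 1 and with scaling by library totals (0.0557). Removing the trend moved the TCA median relative to all genes only from -0.21 to -0.19, with 4 genes lower. For fatty acid oxidation it went from -0.27 to -0.14, with 3 genes lower. Of 23 glycolysis genes, 3 fell, with lactate dehydrogenase A (Ldha) going from 2938 ± 149.0 to 1929.7 ± 78.2 CPM (a call lost with no filter), and the list did not pass (camera adjusted p = 0.18). It passed without control replicate 2 (6 genes lower, adjusted p = 0.00907) and without FK866 replicate 1 (4 genes lower, adjusted p = 0.0232). Of 20 HIF-1 targets, 4 rose and 2 fell (6 and 2 adjusted over the list alone), among them Mxi1 (1.59) and Fam162a (-1.01), with a camera adjusted p of 0.208. For Fam162a, 19.8% of the exon bases overlap a gene on the other strand. With the length and GC trend removed, Fam162a was at -0.63 and Ldha at -0.35 in place of -0.61. That list passed without FK866 replicate 2 (5 genes higher, adjusted p = 0.0232), and with the stricter filter 7 of its genes were called higher.

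FOXO transcription factors are active when PI3K and AKT signalling is low. Of 22 of their targets measured, 8 were higher and 0 lower (9 and 0 adjusted over the list alone), with a median log2 fold change of 0.69 and a camera adjusted p of 9.87e-10 (adjusted p = 0.60 with an estimated correlation). Txnip, an α-arrestin that like Arrdc4 restrains glucose uptake, went from 65.0 ± 3.05 to 388.5 ± 18.1 CPM (log2 2.58 ± 0.13, SE, edgeR adjusted p = 0.000118). For Txnip, 19.4% of the exon bases overlap an antisense gene whose reads cannot be told apart here. Bcl2l11, which encodes the pro-apoptotic protein BIM, went from 27.3 ± 1.86 to 174.8 ± 8.64 CPM (log2 2.68 ± 0.14, SE, edgeR adjusted p = 0.000125). Bcl6 and the PI3K inhibitor gene Pik3ip1 (log2 1.88) were the next members by adjusted p.

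Of 32 ATF4 target and amino acid response genes, 14 were higher and 1 lower (14 and 2 adjusted over the list alone), with a median of 0.40 and a camera adjusted p of 2.71e-06 (adjusted p = 0.72 with an estimated correlation). Asparagine synthetase (Asns) went from 58.4 ± 13.6 to 152.2 ± 25.4 CPM, mitochondrial PEPCK (Pck2) rose by 1.68, the amino acid transporter subunit Slc3a2 by 1.19, the eIF2α phosphatase subunit Ppp1r15a by 1.36 and Ddit3, which encodes CHOP, by 1.29 on the log2 scale. Without FK866 replicate 1, 7 of these genes were called higher. In the unfolded protein response, 3 of 22 genes rose and 1 fell, also when adjusted over the list alone, with the sensor Ern1 at 1.07 and the chaperone Sdf2l1 at -0.81 (camera adjusted p = 0.332). With the length and GC trend removed Sdf2l1 was at -0.44 and that list passed (7 genes higher, adjusted p = 0.0474), and with the stricter filter 8 genes were called higher without a list call. Of 29 genes of mTORC1, AMPK and autophagy, 7 rose and 1 fell (9 and 2 adjusted over the list alone), including folliculin (Flcn, 1.44), the autophagy receptor Sqstm1 (1.12), Atg12 (0.95) and Sesn3 (0.87). That list had a camera adjusted p of 0.00111 (adjusted p = 0.60 with an estimated correlation), with 4 genes called higher without FK866 replicate 1. For Sqstm1, 17.3% of the exon bases overlap a gene on the other strand. Of 28 NRF2 and redox genes, 4 rose and 2 fell (4 and 8 adjusted over the list alone), with Nfe2l2 itself at 0.95 (camera adjusted p = 0.45). The median of that list was -0.24 and its mean 0.02.

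Among NF-κB response genes, 5 of 20 rose and 1 fell (10 and 1 adjusted over the list alone). The rises included Tnfaip3, which encodes the inhibitor A20, from 89.2 ± 27.2 to 360.3 ± 52.6 CPM, Tnfrsf9 (log2 2.03) and Rel (1.46), and the fall was in Bcl3 (-1.04), whose product also acts within the NF-κB pathway. The camera adjusted p was 2.50e-05 (adjusted p = 0.72 with an estimated correlation). The number called higher was 3 without control replicate 2 or FK866 replicate 1 and 9 without control replicate 1 or FK866 replicate 2, and it was 9 with scaling by library totals or by upper quartile, 10 with the stricter filter and 8 with the length and GC trend removed. Of 22 immediate early genes, 7 rose and 1 fell, also when adjusted over the list alone, with Fosl2 at 2.08, Egr1 at 1.98, Atf3 at 2.11 and Klf6 at 1.21 (camera adjusted p = 0.00912; adjusted p = 0.72 with an estimated correlation). This list call was lost without control replicate 2 (adjusted p = 0.116) and without FK866 replicate 1 (0.113).

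Genes that define ILC2s moved in both directions. Of 27 measured identity genes, 3 rose and 5 fell (5 and 10 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.679, median -0.22, mean 0.01). Without control replicate 2, 5 rose and 10 fell. Rora, which encodes a transcription factor required for ILC2 development (ENSMUSG00000032238, chromosome 9, 68653786 to 69388246, plus strand), went from 355.9 ± 26.4 to 1156 ± 40.1 CPM (log2 1.70 ± 0.12, SE, edgeR adjusted p = 0.000457). Ramp3, a co-receptor for CGRP-family peptides, rose from 10.9 ± 2.43 to 82.0 ± 19.2 CPM. The neuromedin U receptor gene Nmur1 fell from 752.9 ± 16.4 to 333.0 ± 27.2 CPM (log2 -1.18, adjusted p = 0.00147) and arginase 1 (Arg1) by 1.33 on the log2 scale. Gata3, the lineage-defining factor, stood at 1014 ± 95.5 and 770.2 ± 101 CPM (log2 -0.40 ± 0.14, SE, adjusted p = 0.0921) and did not pass. Neither did the IL-33 receptor gene Il1rl1 (0.02), the IL-25 receptor gene Il17rb (-0.61, adjusted p = 0.0516), Il7r (0.64) or Klrg1 (-0.46). Each of these 5 genes was called once control replicate 2 was left out. Without it Gata3 (-0.52, adjusted p = 0.0379), Il17rb (-0.80, adjusted p = 0.0172) and Klrg1 (-0.59, adjusted p = 0.0482) were called lower and Il7r (1.14, adjusted p = 0.00348) and Il1rl1 (0.56, adjusted p = 0.0265) higher. Gata3 was also called lower by limma-voom (adjusted p = 0.0347) and with the length and GC trend removed (adjusted p = 0.0419). Il17rb, Il7r and Klrg1 were also called by limma-voom, Il17rb and Il7r by DESeq2, and Il17rb with either other filter. The control libraries differed widely for Il1rl1 (232.4 ± 106 CPM).

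Il13 fell from 139.4 ± 30.9 to 49.8 ± 21.5 CPM (log2 -1.49 ± 0.28, SE, edgeR adjusted p = 0.0118), with a log2 fold change between -2.01 and -1.10 as each library was left out. Il5, encoded on the same chromosome (chromosome 11, 53720794 to 53725106, plus strand), did not pass, at 627.1 ± 210.1 and 558.8 ± 279 CPM (log2 -0.17 ± 0.32, SE, adjusted p = 0.804), and 27.1% of its exon bases overlap an antisense gene. Areg, which encodes amphiregulin, was at 75.6 ± 23.3 and 77.1 ± 38.2 CPM (log2 0.03 ± 0.32, SE, adjusted p = 0.977). Across 19 effector genes 2 rose and 4 fell (3 and 5 adjusted over the list alone), with Lif the deepest fall and Cxcl2 a rise (1.69), and the list did not pass (camera adjusted p = 0.294). The other riser, Dgat1, is a lipid enzyme and not a secreted product. Without FK866 replicate 1 that list was called lower (5 genes, adjusted p = 0.00158), and without FK866 replicate 2 its members went the other way on balance (adjusted p = 0.83).

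**Figure D2:**
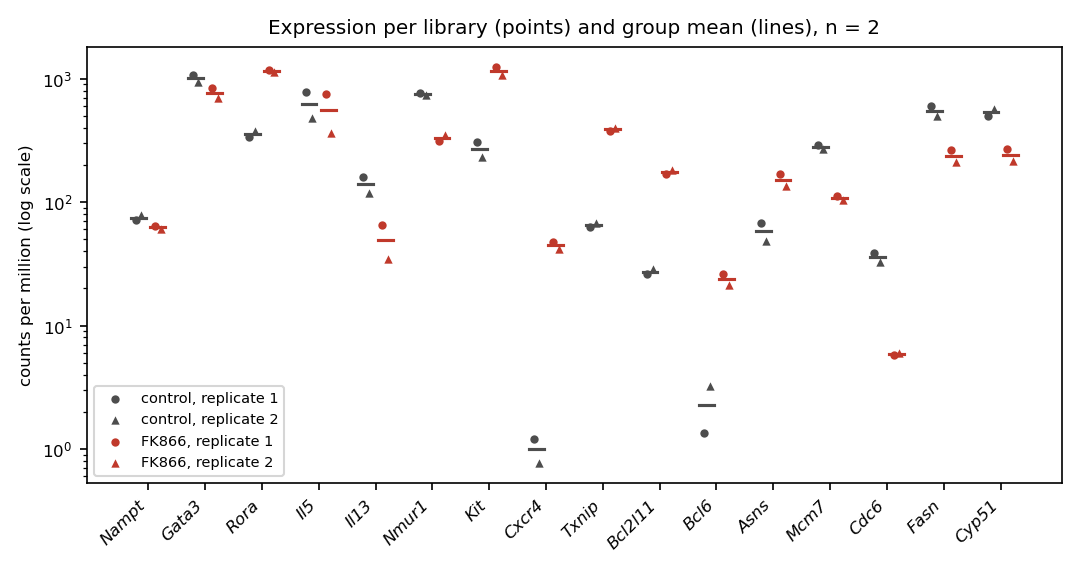
CPM on a log axis for 16 genes in each of the 4 libraries (circles, replicate 1; triangles, replicate 2; grey, control; red, FK866), with a line at each group mean. Kit, Rora, Cxcr4, Txnip, Bcl2l11, Bcl6 and Asns lie higher in both FK866 libraries, Il13, Nmur1, Mcm7, Cdc6, Fasn and Cyp51 lie lower, and the libraries of the 2 groups overlap for Il5.

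In the cell death list, 2 of 26 genes rose, Bcl2l11 and Fas (log2 1.86), and 10 fell, among them Gsdmd (-0.81), with the same counts adjusted over the list alone and no shift of the list (camera adjusted p = 0.213). The falls numbered 6 without FK866 replicate 1, when the list was called lower (adjusted p = 0.0378), 4 without FK866 replicate 2 and 5 with the length and GC trend removed, when Gsdmd was at -0.53. Of 25 p53 targets, 3 rose and 4 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.515), and Cdkn1a, a cell cycle inhibitor, had a log2 fold change of -0.80 that did not pass (adjusted p = 0.0789). Cdkn1a was called lower without control replicate 2 (-1.11), without FK866 replicate 1 (-1.19), by limma-voom and with either other filter. That list was called lower without control replicate 2 (adjusted p = 0.0368) and without FK866 replicate 1 (0.0451). Of 27 type I interferon genes, 6 fell and 0 rose, also when adjusted over the list alone, including Oas3, Xaf1 (-1.50) and Zbp1 (-1.53), and the list did not pass (camera adjusted p = 0.102) except with the stricter filter (0.00926) or with no filter (0.0021). Of 74 ribosomal protein genes, 2 rose, Rpl3 (0.61) and Rps2 (0.39), and 1 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.486). The call of Rps2 was lost without control replicate 2, without either FK866 library, with no filter, with mitochondrial genes left out and by DESeq2, and that of Rpl3 with no filter (adjusted p = 0.166). With the length and GC trend removed, 39 of them were higher and 0 lower (adjusted p = 5.08e-11), Rps2 by 0.76, and with the stricter filter 14 were higher. Reads of these genes may be shared with their many pseudogenes. Ppargc1a was close to the floor, at 0.687 ± 0.504 and 0.965 ± 0.631 CPM.

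Markers of other cell types were examined because the sort and the culture could carry other cells. In the ILC3 list, 4 of 14 genes rose and 0 fell, also when adjusted over the list alone, with a median of 0.55 and a camera adjusted p of 0.00142 (adjusted p = 0.60 with an estimated correlation). The receptor tyrosine kinase gene Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722, plus strand) went from 268.9 ± 53.5 to 1165 ± 119 CPM (log2 2.12 ± 0.16, SE, edgeR adjusted p = 0.000595) and Ltb from 104.6 ± 35.4 to 279.1 ± 23.2 CPM. The other risers, named after their values were seen, were Il17f (2.34), which had 44.7 CPM in FK866, and Il23r (2.05), whose call was lost without control replicate 1 (adjusted p = 0.0639) or FK866 replicate 1 (0.113). Il22 was at 205.7 ± 83.3 and 144.5 ± 98.3 CPM and did not pass (adjusted p = 0.495). With the replicate number as a block, however, Il22 was called lower (-0.63, edgeR adjusted p = 2.27e-05). Il22 was called lower without FK866 replicate 1 (-1.46, adjusted p = 0.0145).

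In the T cell list the costimulatory receptor gene Cd28 rose (log2 1.19) as 1 of 13 genes, while Trbc1 (-0.62) and Trbc2 (-0.23) did not pass (camera adjusted p = 0.73). Trbc1 was called lower without control replicate 1, without FK866 replicate 2, with no filter, by DESeq2 and by limma-voom. In the myeloid list Cd74 (0.56) and Cd68 (1.41, named after its value was seen) rose among 14 genes (camera adjusted p = 0.082). Cd74 was at 0.91 with the length and GC trend removed. Both myeloid calls were lost without FK866 replicate 1, when the list itself passed (adjusted p = 0.0174), as it did without control replicate 2 (0.0267), and Cd74 was also lost without control replicate 1, without FK866 replicate 2 or with no filter. No member passed among 7 genes of B and plasma cells, 10 of ILC1 and NK cells, 8 of epithelium, 14 of stroma and endothelium, 6 of erythroid cells and platelets and 4 of mast cells, basophils and eosinophils. The 5 of these lists with enough genes to test did not pass (camera adjusted p = 0.685, 0.556, 0.73, 0.213 and 0.843). Their most abundant members were Pecam1 (161.5 ± 27.1 and 205.8 ± 26.6 CPM), Gzmb (91.3 ± 28.0 and 59.5 ± 36.1 CPM), Ighm (72.0 ± 20.9 and 46.6 ± 6.5 CPM) and Epcam (47.7 ± 9.07 and 31.0 ± 8.39 CPM). Gzmb and Epcam were called lower without FK866 replicate 2 and with no filter, Ighm without control replicate 1 and with no filter, Epcam and Ighm also by DESeq2, and Pecam1 was called higher with the stricter filter and with the length and GC trend removed. Cd160 of the ILC1 and NK cell list (log2 -0.79) was called lower with no filter, by DESeq2 and by limma-voom. It was at -1.08 without control replicate 1 and -1.05 without FK866 replicate 2. Cd79b of the B cell list (-0.65) was called lower by DESeq2 and by limma-voom. Adjusted over the list alone, 1 gene of B and plasma cells rose and 2 fell, and the counts of the T cell and myeloid lists were 1 and 2 higher. Among 7 nuclear-retained RNAs, Neat1 rose (1.20) and Kcnq1ot1, named after its value was seen and lost without FK866 replicate 1, fell (-0.74), while Malat1 (0.34) did not pass but was called higher without control replicate 2 (0.84) (camera adjusted p = 0.208). Among 12 histone genes, Hist1h2bc rose (2.22) and H1f0 fell (-0.99), the latter lost without FK866 replicate 2 (camera adjusted p = 0.679).

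**Figure D3:**
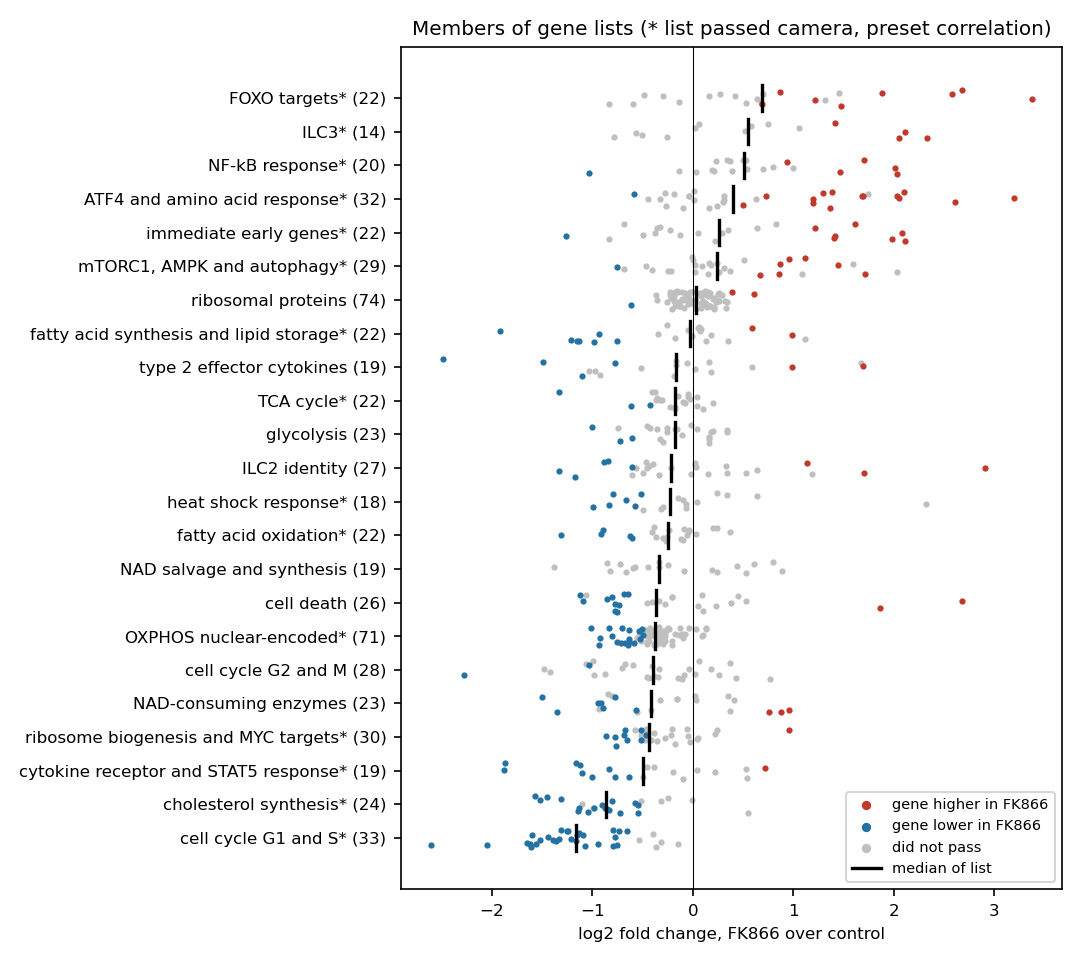
Log2 fold change of each measured member of 23 gene lists fixed in advance, with the number of measured genes in parentheses, members that passed the edgeR test in red (higher) or blue (lower), the list median as a black line and an asterisk where the list passed camera at its preset correlation. The list of G1 and S genes lies farthest to the left, with a median of -1.16, and that of FOXO targets farthest to the right, with a median of 0.69.

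Of the 38 lists tested, 15 passed camera at the preset correlation (6 higher, 9 lower), and 10 of these passed in each of the 4 fits that left out 1 library. With an estimated correlation 0 passed, the smallest adjusted p being 0.60, and 2 lists had an unadjusted p under 0.05 (G1 and S genes, FOXO targets). By fry 0 lists passed for movement in one direction and 29 for change in either direction. With no filter, 23 lists passed camera, among them NAD+ consumers, type 2 effectors, glycolysis, mitochondrially encoded subunits, p53 targets, cell death and G2 and mitosis, which did not pass with the filter. All of these named lists leaned lower. The unfiltered fit tested 45373 genes, whose median log2 fold change was 0.24 in place of 0.03. Camera compares a list with all other genes, so this raised background could contribute to such calls. Every called gene had CPM values that did not overlap between the groups, as did 57.7% of all tested genes, against 33.3% by chance with 2 libraries per group. Of 117 called genes selected by the naming rule, 89 were called in each of the 4 fits that left out 1 library. Of the 27 selected genes that did not pass, 15 were called in at least 1 of these fits. The number of genes called was 1252 without FK866 replicate 1, 1411 without FK866 replicate 2, 2519 without control replicate 1 and 2434 without control replicate 2. With the length and GC trend removed it was 2959, of which 1576 were higher and 1383 lower, so that the share of lower calls was 46.7% in place of 59.7%. That correction moved the median log2 fold change of all tested genes from 0.03 to 0.13.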

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

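The fit without the length and GC trend was chosen after seeing the data, and every other setting before. Each of the 2534 calls that was tested under another setting kept its sign there, and outside the 1.5-fold test 1158 to 2534 of them were called again. The kept signs were nearly fixed in advance and are no separate support, because the groups did not overlap in CPM for any called gene. With these library sizes and 2 libraries per group, 67 of 100 simulated 2-fold changes were recovered among genes with a mean log2 CPM above 2. A gene that did not pass may therefore still have changed, and recovery below that level was not measured. Where no reason is given below, the cause of a change was not tested. The count of genes called stayed within 1.5 times the main one under the other scalings, both filters, DESeq2 (3189), limma-voom (3058) and without mitochondrial genes. The stricter filter gave 1805 higher genes (1632 lower, or 47.5% of calls) with fewer genes tested, and removal of the length and GC trend gave 1576. A test for a change beyond 1.5-fold, a stricter demand by construction, left 403 genes called between FK866 and control, 190 higher and 213 lower. Leaving out 1 library gave 1252 to 2519 genes, 446 to 1046 higher and 725 to 1550 lower. The replicate number as a block gave 5256 genes (2197 higher, 3059 lower), and of the 27 named genes that did not pass without the block 18 passed with it, Gata3 and Myc among them. Deviations from the group means correlated at 0.234 between libraries of the same number, and the second principal component split the libraries by number in both groups. These values leave room for an effect shared by libraries of the same number. No label ties the numbers to a pairing, however, and there are only 2 of each, so the block stayed an alternative.

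With no filter 23 lists passed camera at the preset correlation, against 15 with the filter. The lists were then compared with a background whose median log2 fold change was 0.24, against 0.03 with the filter. On the filtered genes 0 lists passed with an estimated correlation and 0 by fry. Of the tests of single lists and named genes under other settings, 46 and 80 lost their call, 24 and 66 gained one, and 17 and 22 changed direction. Each change of direction was in a result that had not passed. With no filter, Il1rl1 had a log2 fold change of -0.0255 and the lists of ribosomal proteins, T cells and epithelium turned lower (adjusted p = 0.47, 0.749 and 0.729). With the stricter filter Nadk was at 0.0047 and the ILC2 identity list turned higher (adjusted p = 0.972). Areg was at -0.0292 with the replicate block and -0.0593 with limma-voom. With the length and GC trend removed, Il1rl1 was at -0.0472, Il5 at 0.13, Nadk at 0.0084 and Trbc2 at 0.13, and the lists of mitochondrially encoded subunits (adjusted p = 0.817) and NRF2 genes (0.608) turned higher. As each library was left out, log2 fold changes ran from -0.42 to 0.56 for Il1rl1, -0.80 to 0.27 for Il5, -0.59 to 0.46 for Areg, -0.40 to 1.53 for Ppargc1a, -0.23 to 0.0079 for Nadk, -1.46 to 0.0569 for Il22, -0.18 to 0.36 for Xcr1, -0.20 to 0.93 for Xist and -0.0703 to 0.84 for Malat1. The adjusted p ran from 0.609 to 0.76 for the ILC2 identity list, 0.00158 to 0.83 for type 2 effectors, 2.67e-05 to 0.572 for mitochondrially encoded subunits, 0.0368 to 0.927 for p53 targets, 0.116 to 0.926 for ribosomal proteins, 0.60 to 0.927 for T cells, 0.457 to 0.962 for B and plasma cells, 0.115 to 0.962 for ILC1 and NK cells and 0.189 to 0.636 for erythroid cells and platelets.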

Other observations

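The families below were noticed in the table of all genes and tested on the same data, and the tests of the length trend in single lists, of ILC3s and of mast cells were chosen after the results were seen. The other tests, of slopes within groups and of the cell cycle, were written before.

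All 8 measured GIMAP genes, GTPases that support lymphocyte survival, fell in FK866, with a median log2 fold change of -1.16 (camera adjusted p = 3.20e-14 over 6 such families; adjusted p = 0.126 with an estimated correlation). Gimap3 went from 392.6 ± 45.4 to 122.3 ± 14.2 CPM (SD, n = 2) and Gimap4 from 190.2 ± 0.598 to 52.7 ± 9.97 CPM, and both were called in each fit that left out 1 library. Without FK866 replicate 2, 5 of the 8 were called. Of 17 circadian clock genes, 9 rose and 0 fell (median 0.73; camera adjusted p = 1.60e-12; adjusted p = 0.126 with an estimated correlation). Nr1d1, which encodes the repressor REV-ERBα, went from 39.6 ± 4.97 to 139.1 ± 1.49 CPM, Hlf from 66.9 ± 21.7 to 251.2 ± 32.7 CPM and Per1 by 1.79 on the log2 scale. Rora is one of these 17 genes and was already described. The sources used here do not give the clock time at which either group was harvested.

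Of 77 mitochondrial ribosomal protein genes, 27 fell and 0 rose (median -0.38; camera adjusted p = 2.83e-12; adjusted p = 0.208 with an estimated correlation), with Mrpl20 at -1.37 and Mrpl41 at -1.40. The number lower was 13 without FK866 replicate 1, 9 without FK866 replicate 2, and 21, with 6 higher, after removal of the length and GC trend (adjusted p = 3.89e-06). Interferon-inducible GTPases split: of 20, 10 fell, led by Igtp (194.9 ± 0.536 to 45.7 ± 1.77 CPM) and Tgtp2 (-2.05), and 4 rose, including Gbp4 (0.72), which was not called without FK866 replicate 1 (camera adjusted p = 1.02e-05; adjusted p = 0.208 with an estimated correlation). Members of this family have close copies whose reads may be shared between them, a doubt that the 10 genes lower after removal of the length and GC trend do not address. Of 378 zinc finger genes, 32 rose and 9 fell (camera adjusted p = 0.0464; 0.126 with an estimated correlation), a call lost with no filter (0.598), after the length and GC correction (0.149) and without control replicate 1 (0.0596), FK866 replicate 1 (0.0549) or FK866 replicate 2 (0.0878). Of 20 cytosolic tRNA synthetase genes, 4 fell (camera adjusted p = 0.0787), and 0 were called without FK866 replicate 1 or without FK866 replicate 2, while the list passed without control replicate 2 (0.00178), without FK866 replicate 1 (0.0111) and with no filter (0.002).

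Short transcripts tended to be lower and long ones higher in FK866: over 8 bins of protein-coding genes the median log2 fold change went from -0.40 at a median length of 1226 nt to 0.21 at 7797 nt. Bias in length or GC content is not the whole source of the fall in G1 and S genes, whose median stayed 1.27 below that of all genes (-1.2652) once the trend was removed. The correction could move this list little, because its median transcript is 3431 nt. Bins of near length had medians of -0.13 (3160 nt) and -0.06 (3778 nt). For the nuclear-encoded genes of oxidative phosphorylation, bias in length or GC content cannot be told apart from a change in the cells. With the trend removed, their difference from all genes shrank from -0.40 to -0.1569 (-0.16), and the list call ended by a narrow margin (camera adjusted p = 0.064). The 74 ribosomal protein genes are about as short, with a median transcript of 1107.5 nt against 1005 nt. They did not lie lower before the correction (median 0.03) and were at 0.35 after it. Whether they escaped a bias or rose despite it was not tested. Random variation in how libraries capture long transcripts also stays open: the slope per log2 unit of length was at most 0.0828 between libraries of a group against 0.152 to 0.260 between groups, all in one direction, but with a pair of libraries per group this margin was too small to decide. A response of the cells to FK866 that favours long transcripts may also contribute and was not tested apart from the treatment.

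Kit and 3 other genes of the ILC3 list were higher in FK866. Mast cells, which also carry Kit, are argued against by 14 markers of mast cells, basophils and eosinophils, of which 4 passed the expression filter: their summed level reached 3.41 CPM in an FK866 library against a rise in Kit of 896.3 CPM. ILC3s mixed into the FK866 cultures cannot be told apart from a change in the ILC2s. For 1 of 2 genes tested, Il22, the log2 fold change plus 2 SE (0.34) stayed below the rise of Kit (2.12). For Il23r (2.05) it did not. This test cannot decide, because added cells need not raise genes with unlike starting levels by the same log2 amount. In CPM, Il23r went from 1.17 to 4.85 and Il22 from 205.7 to 144.5, while Kit rose by 896.3. The cells had been sorted as ILC2s, with a gate that is not given in the sources used here, and Kit already stood at 268.9 CPM in controls. Another hypothesis that remains is that the ILC2s themselves, or a subset already present, raised Kit, Il17f and Ltb under FK866, which bulk RNA may not separate.

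G1 and S genes fell almost as a block while few genes of G2 and mitosis were called. Whether a smaller share of cycling cells lowered both lists alike cannot be decided here. In each of the 4 pairs of an FK866 and a control library the mean log2 change of G1 and S genes lay further down. The excess was -0.3975 (-0.40) at the least, which met the cut set in advance, and -0.96 at the most. The smallest excess lay only narrowly beyond the 0.33 seen between the controls (0.23 between the FK866 libraries). The 4 pairs share libraries and are not independent. Over these pairs the mean log2 change of the G2 and mitosis list itself ran from -0.88 to 0.0011. Lower expression of the G2 and mitosis genes could limit their calls and cannot be told apart from a smaller change: 75% of 8 G1 and S genes chosen as closest in expression were called (6 genes), but the match failed, with a median log2 CPM of 3.58 against 2.05. A hypothesis that fits these values is that entry into S phase had fallen off before cells already in cycle had passed through mitosis, and no time course was analysed here to test it.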
